A study of Mus musculus with 8 samples.

How the data were processed

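Total RNA from normal colon and from colon tumors of wild-type C57BL/6 mice and of mice labelled caspase-12 deficient was hybridized, as Cy3-labelled material, to Illumina MouseRef-8 v2 arrays. Per the labels there were 2 arrays in each of 4 groups, 8 arrays in all. Nothing in the labels says that the replicates of a group are separate animals, so the p-values measure only the spread between these samples, which may be technical. How the tumors arose or were induced, where along the colon the samples were taken, and which slides the arrays shared are not given in the sources used here.

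The deposited non-normalized table held, per the file headers, a signal intensity and a detection p-value for each of 25697 probes on each array. The submitters' processing notes named BeadStudio, version 3.2.7. A deposited series table held log2 values. On every probe these log2 values equalled the log2 intensity minus the log2 of the array's mean intensity to within 1.7e-05, and they were used as an alternative only. No columns were left unused. Of the probes, 23978 carried 1 gene symbol and 1719 carried none. The mean intensity per array was 1131.75 and 1165.05 in wild-type normal colon, 1112.5 and 1156.98 in caspase-12 deficient normal colon, 1133.75 and 1138.7 in wild-type tumors, and 1181.52 and 1144.93 in caspase-12 deficient tumors. The number of arrays limits the precision.

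The intensities were background corrected and normalized with neqc in limma 3.58.1 under R 4.3.3. This step took the mean and spread of the negative controls from the detection p-values (798 steps), applied the normexp model with an offset of 16, quantile normalized the arrays and took log2. Probes with a detection p under 0.01 on at least 2 of the 8 arrays were tested, which left 13327 probes. Of these, 12571 had a symbol, covering 9341 genes. A gene was represented by its tested probe with the highest mean over the 8 arrays.

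One limma model of the 4 group means gave tumor minus normal in each genotype, caspase-12 deficient minus wild type in each tissue, and the genotype by tissue interaction, with 4 residual and 3.55 prior degrees of freedom. Additive limma models gave the tumor difference over both genotypes and the genotype difference over both tissues. P-values were adjusted by the Benjamini-Hochberg method over all probes tested, with a threshold of 0.05, and all tests were two-sided unless stated. On simulated data with 200 changed probes in each of 10 simulations, the procedure recovered between 9.55% and 11.0% of changes of 1 log2 unit, between 83.9% and 85.7% of changes of 2 log2 units and between 96.8% and 97.0% of changes of 3 log2 units. Between 5.04% and 6.58% of the calls there were false. The simulated arrays had the same spread in every group. In the data the SD of the log2 difference between replicates was 0.709 in wild-type and 0.762 in deficient tumors. It was 0.475 in wild-type and 0.480 in deficient normal colon, so the simulated rates may not hold for single comparisons.

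Before the data were examined, 33 gene lists were fixed, covering epithelial and stromal cell types, immune cells, signalling and metabolic pathways, blood, exocrine pancreas, position along the colon, chromosomal neighbours of Casp12 and sex. After the data were seen, 3 lists were added (squamous epithelium, melanocyte and hair, and skeletal muscle). Each list was tested with camera, with the inter-gene correlation preset at 0.01 and again with an estimated correlation, and with fry, adjusted over the lists within a comparison. With the preset value camera compares the list with all other genes. Fry asks only whether the members of a list move one way on balance. No list passed camera with an estimated correlation in any comparison.

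The named genes followed a rule fixed before the data were examined. Casp12 came first. For each tumor, genotype and interaction comparison the rule took the 12 largest rises and the 12 largest falls among named genes past the threshold with no overlap between the arrays of the groups, leaving out predicted genes and clone names. It added up to 4 members of each described list with the largest differences, and, for the genotype comparisons, Casp1, Casp4, Il1b, Il18, Nod2 and Ripk2 where tested. From the additive models it took none. For wild-type tumors, where nothing passed, the 12 genes with the smallest unadjusted p were chosen after their values were seen.

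A probe was taken as above background on an array when its detection p was under 0.01. Where a probe was above background on no array of a group, only a lower bound on the fold change is given ("at least"), made by setting that group at the lowest intensity called above background. The log2 difference printed beside such a bound is the difference of the normalized means, and is not itself a bound.

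The alternatives tried were array weights, no background correction, an offset of 50, median scaling, cyclic loess, the deposited series values, no filter on dim probes, probes detected on all 8 arrays, a minimum log2 difference of 1, eBayes with trend and robust settings, models of the arrays of the compared groups alone, a replicate block, means over all probes of a gene, and leaving out each array in turn. With 1 array left in a group, that array was assumed to vary like those of the other groups. A comparison of caspase-12 deficient tumors with wild-type normal colon was added after the data were seen.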

Results

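Gene expression was measured in normal colon and in tumors from wild-type mice and from mice labelled caspase-12 deficient, with 2 arrays per group. The series is about inflammatory caspases in gut homeostasis, colitis and colon cancer, and its design sets tumor against normal tissue in the presence and absence of caspase-12. Casp12, the targeted gene, gave little signal anywhere. Its probe (ILMN_2989535) read 5.84 and 5.83 log2 units in wild-type normal colon, 6.50 and 7.21 in caspase-12 deficient normal colon, 5.73 and 5.88 in wild-type tumors, and 6.97 and 5.96 in caspase-12 deficient tumors. It was above background on 0 of the 4 wild-type arrays and on 1 of the 2 arrays of each deficient group. Both deficient arrays lay above both wild-type arrays in each tissue, at least 1.01-fold in normal colon (limma adjusted p = 0.213) and with no bound above 1 in tumors (adjusted p = 0.256), and neither difference passed. The probe does not check the labels, because its position relative to the deleted part of the gene is not given in the sources used here. Between 43.7% and 49.1% of all probes were above background on each array.

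The caspase-12 deficient tumors stood apart from the other samples on the first principal component, with wild-type tumor replicate 1 between them and the rest. The first principal component, with 49.9% of the variance, placed the deficient tumors at 97.2 and 78.6, deficient normal colon at −41.1 and −40.5, wild-type normal colon at −30.2 and −37.1, and the wild-type tumors at 7.08 and −34.0. The second, with 22.8%, placed the wild-type tumors highest at 54.2 and 35.2, wild-type normal colon at 20.6 and 14.2, the deficient tumors at −16.0 and −7.46, and deficient normal colon at −44.5 and −56.2. Across probes, replicates correlated at r = 0.976 in wild-type normal colon, 0.976 in deficient normal colon, 0.945 in wild-type tumors and 0.938 in deficient tumors. Wild-type tumor replicate 2 correlated at 0.972 and 0.973 with the wild-type normal arrays, and replicate 1 at 0.927 and 0.922. Probes are not independent replicates.

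In caspase-12 deficient mice, the largest rises in tumors over normal colon included single neutrophil, chemokine and squamous epithelium genes. The steepest falls included single enzymes and transporters. S100a8, a calcium-binding protein abundant in neutrophils, rose by 7.12 log2 units (SE 0.47, adjusted p = 4.86e-04), from 7.90 ± 0.774 to 15.02 ± 0.135 (SD, n = 2 arrays each). Its partner S100a9 rose by 7.41 (SE 0.77, adjusted p = 0.00148), and lactoferrin (Ltf), a neutrophil granule protein, by 8.42 (SE 2.05, adjusted p = 0.0278). The neutrophil chemokine Cxcl5 was below background in normal colon and rose at least 70.9-fold (log2 difference 7.55, SE 1.09, adjusted p = 0.00462). Arginase 1 (Arg1) rose by 7.31 (SE 2.10, adjusted p = 0.0480). The other largest rises were Psca (7.47) and the squamous genes Krtdap (at least 103-fold), Lor (7.12), Calm4 (at least 41.4-fold), Krt14 (6.93), Serpinb11 (at least 28.4-fold) and Lgals7 (at least 63.9-fold). The steepest falls were in the cytochromes P450 Cyp2c65 (at least 120-fold lower, adjusted p = 4.12e-04) and Cyp2c55, which fell by 7.54 (SE 0.46, adjusted p = 4.12e-04). The bile acid transporter subunit Slc51a fell at least 120-fold and Prap1 at least 59.5-fold. The water channel Aqp8 fell by 6.55 (SE 0.62, adjusted p = 0.00103), the hydroxyacid oxidase Hao2 by 6.42, the sulfotransferase Sult1d1 by 6.27, the peroxisomal thiolase Acaa1b by 5.77 and carbonic anhydrase 4 (Car4) by 5.68 (SE 1.09, adjusted p = 0.0123). Slc30a10 fell at least 28.3-fold, Hkdc1 at least 33.4-fold and Defb37 at least 23.1-fold. For each of these 24 genes both tumor arrays lay on the same side of both normal arrays, which the rule for choosing them required. Slc51a, Prap1, Cyp2c65, Acaa1b and Defb37 were also called higher in deficient than in wild-type normal colon, and S100a8 lower. The tumor minus normal differences of these genes thus start from a shifted baseline.

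Of the 13327 probes tested in the deficient mice, 1160 rose in tumors (911 genes) and 1421 fell (1088 genes). Of these, 78 of the rises were called lower, and 108 of the falls higher, in deficient than in wild-type normal colon. Rises made up 44.9% of the changes, but 32.3% with median scaling, 50.1% with cyclic loess and 55.8% with the deposited series values, so the balance of rises and falls depended on the scaling. The median of all probes was −0.26 with median scaling and 0.11 with the deposited values, against −0.02. Without deficient normal replicate 1 or 2 the count was 950 or 809, and without deficient tumor replicate 1 it was 1549. Of the 24 named genes 15 kept their call whichever array was left out, and 9 were not called without deficient normal replicate 2, among them Ltf, Krtdap, Psca, Arg1, Krt14 and Car4.

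Most measured cytokines and chemokines rose in the deficient tumors, 17 of 24, and none fell (19 rose adjusted over the list alone), with a median of 2.54 (adjusted p = 0.113 with an estimated correlation). Besides Cxcl5, these included Cxcl1 (at least 53.9-fold), Il1b (5.83, SE 0.71) and Cxcl2 (at least 5.67-fold). Of 11 neutrophil genes 9 rose (10 adjusted over the list alone), with Retnlg (at least 17.04-fold) next to Ltf, S100a9 and S100a8. Of 14 matrix proteases and inhibitors 12 rose (13 adjusted over the list alone), led by Mmp10 (at least 58.2-fold), Mmp7 (4.86), Mmp13 (3.86) and Timp1 (3.58). Of 7 mast cell genes 6 rose (7 adjusted over the list alone), led by histidine decarboxylase (Hdc, at least 72.4-fold). For each of these 4 lists camera with the preset correlation called a rise, and the call was lost with an estimated correlation (adjusted p = 0.113 each). Of 13 Paneth and antimicrobial genes 7 rose and 1, the immunoglobulin transporter Pigr, fell (8 rose and 2 fell adjusted over the list alone; adjusted p = 0.196 with an estimated correlation). Beyond the S100 genes that list was led by intelectin 1 (Itln1, at least 39.5-fold) and Mmp7. Of 17 macrophage genes 8 rose, led by Arg1 and Fcer1g (2.09), and Cd163 fell by 2.04 (11 rose and 2 fell adjusted over the list alone; adjusted p = 0.202 with an estimated correlation). In the wild-type tumors Arg1 did not follow this list. Of 18 genes of the NOD and NF-kB pathway 7 rose (7 adjusted over the list alone), with the feedback inhibitors Tnfaip3 (1.62) and Nfkbie (at least 2.39-fold) at the top (adjusted p = 0.215 with an estimated correlation).

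Wnt target genes also rose in the deficient tumors. Of 14 measured, 11 rose and none fell (12 rose adjusted over the list alone), with a median of 2.76 (camera adjusted p = 4.80e-06 with the preset and 0.325 with an estimated correlation). Notum, a secreted Wnt inhibitor, rose at least 23.1-fold, Apcdd1 at least 17.6-fold, Wif1 by 4.25 (SE 0.86) and Prox1 at least 12.5-fold. Of 22 cell cycle genes Mcm2 (1.31) and Rrm1 (0.87) rose (1 adjusted over the list alone), with a median of 0.61 (adjusted p = 0.00617 with the preset and 0.455 with an estimated correlation).

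Many genes of the differentiated epithelium fell in the deficient tumors, though no list call held with an estimated correlation and some members rose. Of 20 absorptive colonocyte genes 14 fell (14 adjusted over the list alone; adjusted p = 0.202 with an estimated correlation), including Sult1a1, which fell by 4.90, and Tmigd1, which fell by 4.79, next to Aqp8 and Car4. The proton pump Atp12a (3.54) and the sodium channel subunit Scnn1g (1.32) rose (2 adjusted over the list alone). Of 22 xenobiotic metabolism genes 15 fell and 1, Cyp2b10, rose (18 fell and 1 rose adjusted over the list alone), with a median of −2.86. Of 16 fatty acid oxidation genes 12 fell (14 adjusted over the list alone), among them Acaa1b, Ehhadh (at least 7.29-fold) and Acaa2, which fell by 2.60. With an estimated correlation the adjusted p was 0.184 for xenobiotic and 0.113 for fatty acid oxidation genes. Of 12 enteroendocrine genes 8 fell (8 adjusted over the list alone), including the hormones somatostatin (Sst), which fell by 5.27, and proglucagon (Gcg), which fell by 4.75, while the transcription factor Isl1 rose at least 32.0-fold (adjusted p = 0.336 with an estimated correlation). Of 12 goblet cell genes 4 fell (4 adjusted over the list alone). These were Agr2, Clca1, Spdef and Galnt12, with log2 differences of −2.66, −2.48, −2.13 and −2.01 (adjusted p = 0.366 with an estimated correlation).

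Some markers of other tissues differed too. Of 32 squamous epithelium genes, a list added after the data were seen, 21 rose and none fell (29 rose adjusted over the list alone), with a median of 5.06 and members such as Trp63 (at least 25.4-fold) and Rptn (at least 43.1-fold). Camera called this rise with the preset correlation, and the adjusted p was 0.451 with an estimated correlation. Skeletal muscle genes, also added, had a median of 3.36 over 12 members, of which none rose and Des fell by 0.91 (0 adjusted over the list alone; adjusted p = 0.101 with the preset correlation). That median came from replicate 1 at 6.98 against −0.33 in replicate 2. The 1 measured melanocyte and hair gene, Krt27, differed by 1.66 (adjusted p = 0.439), with replicate 1 at 5.21 and replicate 2 at −0.02 from the wild-type normal mean. Of 5 blood genes Alas2 rose at least 4.24-fold and Ppbp, at least 87.7-fold higher, did not pass (2 adjusted over the list alone; adjusted p = 0.336 with an estimated correlation). Of 5 distal colon genes Hoxd12 (at least 5.01-fold) and Hoxd13 (at least 2.10-fold) rose (3 adjusted over the list alone; adjusted p = 0.336 with an estimated correlation), and of 5 small intestine and proximal genes Hoxb6 (at least 9.20-fold), Sis (at least 4.85-fold) and Cyp4b1 (at least 9.07-fold) fell (3 adjusted over the list alone; adjusted p = 0.113 with an estimated correlation).

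Lists of stromal and B cells went both ways in the deficient tumors. Of 19 fibroblast and matrix genes 6 rose, led by Col1a1 (2.24), and Fap fell by 1.93 (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.409 with an estimated correlation). Of 12 endothelial genes 3 rose, namely Egfl7 (1.42), Cdh5 (at least 1.17-fold) and Esam (1.10) (4 adjusted over the list alone; adjusted p = 0.455 with an estimated correlation). Of 13 B and plasma cell genes 3 rose, namely Fcmr (at least 3.73-fold), Cd79b (at least 3.85-fold) and Cd22 (1.09) (4 adjusted over the list alone; adjusted p = 0.455 with an estimated correlation). Of 15 smooth muscle genes 5 fell, led by Pln, which fell by 2.51 (9 adjusted over the list alone; adjusted p = 0.416 with an estimated correlation). Of 8 enteric neuron and glia genes 5 fell, led by Prph, which fell by 1.89 (6 adjusted over the list alone; adjusted p = 0.336 with an estimated correlation). Of 8 adipocyte genes 4 fell, namely Cidec, Pparg, Acvr1c and Lpl (4 adjusted over the list alone; adjusted p = 0.398 with an estimated correlation). Leaving out 1 array ended the preset call for blood (adjusted p = 0.0596 without deficient normal replicate 1 and 0.198 without deficient tumor replicate 1), endothelial (0.0617 without deficient normal replicate 2 and 0.204 without deficient tumor replicate 2), adipocyte (0.128 and 0.277 in the same order) and fibroblast genes (0.0618 without deficient tumor replicate 2).

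**Figure D1:**
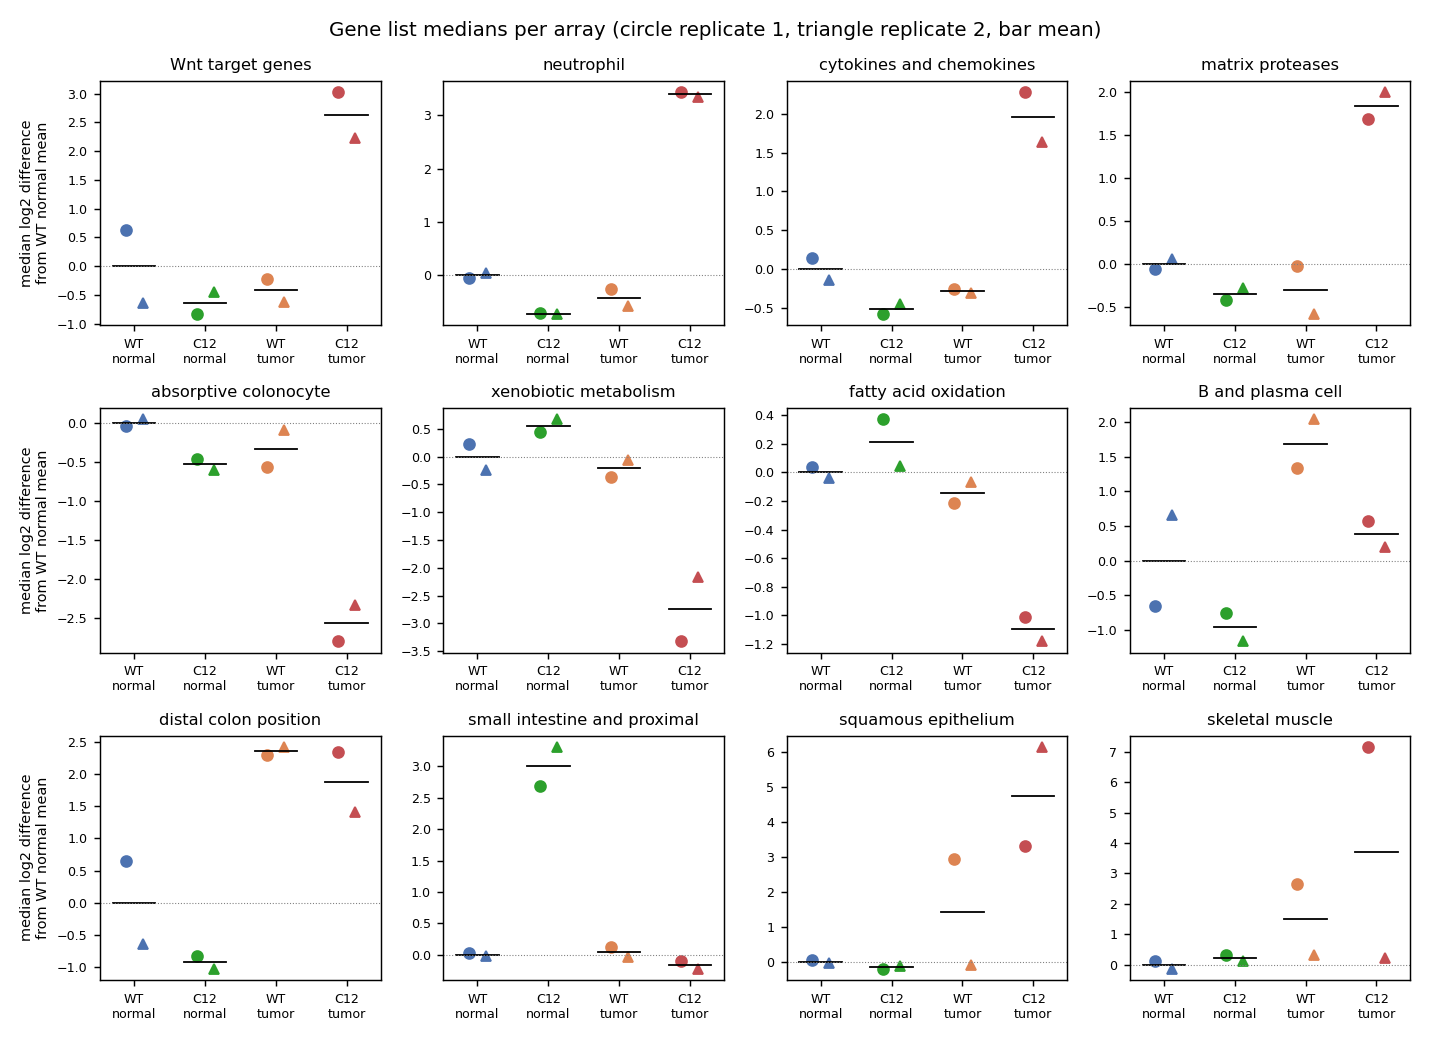
Median log2 difference of each array from the wild-type normal mean, for 12 gene lists, with circles for replicate 1, triangles for replicate 2 and bars for the group mean; y axes differ between panels. Wnt target genes stood at 3.03 and 2.23 in the deficient tumors and at −0.23 and −0.62 in the wild-type tumors.

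Inflammasome genes did not move one way. In deficient tumors Il1b rose and Mefv rose at least 1.03-fold, while the adaptor Pycard fell by 2.13, Casp1 by 1.12 (SE 0.25, adjusted p = 0.0209) and Txnip by 0.96 (2 rose and 3 fell adjusted over the list alone). Over the 12 measured members the median was −0.34, the mean was 0.16 and camera pointed down (adjusted p = 0.424). Other lists without a call were interferon-stimulated genes (median 0.44, adjusted p = 0.213), MHC class II (0.82, adjusted p = 0.0597), T cell (0.60, adjusted p = 0.0901), immediate early genes of tissue handling (0.35, adjusted p = 0.110), ER stress (−0.05, adjusted p = 0.337), glycolysis (0.14, adjusted p = 0.744) and sex-linked genes (−0.43, adjusted p = 0.132). Exocrine pancreas genes were not called as a list (median 0.50, adjusted p = 0.132), though Pnliprp1 (at least 59.6-fold) and Rnase1 (at least 17.2-fold) rose. The chromosomal neighbours of Casp12 had a median of 0.52 (adjusted p = 0.0204 with the preset and 0.409 with an estimated correlation, and 0.186 without deficient normal replicate 1). Their risers were Mmp10, Mmp7, Mmp13, Mmp12 and Yap1, of which the metalloproteases are also in the protease list.

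In wild-type mice no probe passed between tumor and normal colon. In limma 1154 probes had an unadjusted p under 0.05 and the lowest adjusted p was 0.0927. The genes with the smallest p-values were picked after their values were seen. Fcmr, the IgM Fc receptor, was higher by 3.73 (SE 0.46, adjusted p = 0.1001, n = 2 arrays each), Cxcr5, the homing receptor of follicular B cells, by 2.64 (SE 0.35, at least 3.37-fold) and Prkcb by 2.39 (SE 0.33). H2-Eb2 (at least 2.18-fold), Dusp2 (at least 2.08-fold), Gpr83 (at least 3.62-fold), Pik3ip1 (at least 1.84-fold), Serpina1e (at least 1.10-fold), Scnn1g (1.84, SE 0.21) and Ank1 (2.14) were also higher, as was Serpina1b (log2 difference 1.74, no bound above 1), and Btn1a1 was lower (at least 1.82-fold). Without wild-type tumor replicate 2 the count was 105, of which 35 were higher and 70 lower, with Trp63 (6.65), Col17a1 (5.86) and Sct (−4.39) among them.

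Camera with the preset correlation called lists in the wild-type tumors, but no call held with an estimated correlation (adjusted p = 0.773 for each fixed list called) and fry called none of the fixed lists. B and plasma cell genes had a median of 1.75 over 13 members (7 rose adjusted over the list alone; camera adjusted p = 7.26e-05), with Fcmr, Blk (at least 3.50-fold) and Cxcr5 highest. With only the probes detected on all 8 arrays their median was 0.00 (0.00286 before rounding) and camera pointed the other way (adjusted p = 0.873). MHC class II genes were positive in 8 of 8 members (median 0.96, 1 adjusted over the list alone, adjusted p = 1.77e-04). Smooth muscle (median 0.74, 0 adjusted over the list alone, adjusted p = 1.77e-04), fibroblast (0.53, 2 adjusted over the list alone, adjusted p = 0.00191), endothelial (0.39, 0 adjusted over the list alone, adjusted p = 0.0230), macrophage (0.29, 0 adjusted over the list alone, adjusted p = 0.0329) and NF-kB lists (0.18, 0 adjusted over the list alone, adjusted p = 0.0357) were higher. Distal colon genes had a median of 2.37 (3 rose adjusted over the list alone, adjusted p = 0.00671), with Hoxd13 (at least 5.51-fold), Hoxd10 (3.28) and Hoxd12 (at least 2.39-fold). Goblet cell genes (median −0.97, 2 fell adjusted over the list alone, adjusted p = 5.44e-04), Paneth and antimicrobial genes (−1.40, 3 fell, adjusted p = 0.00143), enteroendocrine genes (−1.09, 0, adjusted p = 0.00191) and cell cycle genes (−0.31, 0, adjusted p = 0.0161) were lower, with Ang4 (−4.34), Reg3b (−3.55) and Reg3g (−3.50) lowest. Wnt target genes had a median of −0.42, with 2 of 14 members positive (adjusted p = 0.319). Squamous genes had a median of 1.34 (adjusted p = 4.03e-04 with the preset and 0.663 with an estimated correlation), which came from replicate 1 at 2.94 against −0.11 in replicate 2. Skeletal muscle genes had a median of 1.54 (adjusted p = 0.0296 and 0.663), with the replicates at 2.67 and 0.32.

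Of the 14 lists called in wild-type tumors with the preset correlation, 4 kept the call whichever array was left out. Without wild-type tumor replicate 2 the call ended for MHC class II, Paneth, distal colon, NF-kB, endothelial, macrophage and cell cycle genes (adjusted p from 0.0882 to 0.385). Without replicate 1 it ended for NF-kB (0.171), squamous and skeletal muscle genes (0.342 each). Without wild-type normal replicate 1 it ended for MHC class II and fibroblast (0.0506 each), NF-kB (0.0696) and macrophage genes (0.237), and without replicate 2 for NF-kB (0.0522), skeletal muscle (0.0615), endothelial (0.0729) and cell cycle genes (0.951).

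In normal colon the genotypes differed in single genes, among them homeobox genes of position along the gut. In deficient mice the transcription factor Osr2 was higher by 6.39 (SE 0.76, adjusted p = 0.00805, n = 2 arrays each), and the homeobox genes Hoxb7 (at least 22.9-fold, adjusted p = 0.00681), Hoxb6 (at least 6.94-fold, adjusted p = 0.00166) and Hoxd4 (at least 7.62-fold, adjusted p = 0.00508) were higher too. Slc51a rose by 5.71 (SE 0.45, adjusted p = 0.00166), Cyp2c65 by 4.50, Prap1 by 4.41 and neurotensin (Nts) by 3.65, and Defb37 (at least 17.4-fold), Acaa1b (at least 36.3-fold), St3gal5 (at least 5.81-fold) and Ugt8a (at least 4.07-fold) were higher. Lower in deficient normal colon were Atp12a, which fell by 5.81 (SE 0.29, adjusted p = 2.01e-04), Nxpe4 (at least 45.6-fold, adjusted p = 1.64e-04), the aspartic protease Ctse, which fell by 4.82 (SE 0.37, adjusted p = 0.00166), Clic6, which fell by 5.89, Cyp2d12, which fell by 4.32, and Cyp2c67, which fell by 4.22. The transglutaminase Tgm3 (at least 26.1-fold), B3gnt7 (at least 15.7-fold), Mptx1 (at least 24.1-fold), Sval1 (at least 10.7-fold), Anxa8 (at least 16.4-fold) and Pla2g4f (at least 16.2-fold) were lower as well. Among further homeobox genes, looked at after the data were seen, Hoxb4 (3.15), Hoxd8 (at least 5.94-fold), Hoxd9 (at least 4.11-fold), Hoxb2 (at least 2.89-fold) and Hoxc6 (at least 2.20-fold) were higher, Hoxa9 (at least 3.54-fold) and Hoxa13 (at least 4.15-fold) were lower, and Hoxd10 differed by 2.20 (adjusted p = 0.0752). Both deficient arrays lay on the same side of both wild-type arrays for every named gene that passed, which the rule required of the genes it picked by size.

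Of the inflammatory caspase genes, Casp1 differed by 0.05 between the genotypes in normal colon (SE 0.25, adjusted p = 0.956). The best expressed Casp4 probe (ILMN_1254655) differed by −1.08 (SE 0.33, adjusted p = 0.1502) in normal colon and by −1.08 (SE 0.33, adjusted p = 0.0599) in tumors. Another Casp4 probe, ILMN_2811737, was below background on all 4 deficient arrays, at least 23.7-fold lower than wild type in normal colon (adjusted p = 1.64e-04) and at least 29.9-fold lower in tumors (adjusted p = 2.10e-04). A further Casp4 probe, ILMN_2811746, differed by −0.86 (adjusted p = 0.145) and −1.05 (adjusted p = 0.0304). ILMN_1254655 and ILMN_2811746 were thus lower by far less and stayed above background on every array. This argues against lower expression of the whole gene as the sole reason for the drop of ILMN_2811737. Probe sequences are not given in the sources used here. A different sequence in the deficient mice was therefore not told apart from lower expression of the part that probe reads. Il18 fell by 2.32 in deficient normal colon (SE 0.41, adjusted p = 0.0368). That call was lost without any 1 of 6 arrays, the wild-type arrays and the deficient normal arrays (adjusted p from 0.0534 to 0.206), and the difference was −1.73 without deficient normal replicate 1. Il1b differed by −1.85 (SE 0.71, adjusted p = 0.234).

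Across all probes 134 were higher in deficient normal colon (116 genes) and 158 lower (125 genes), and the higher ones made up 45.9%, but 37.7% with median scaling and 52.8% with the deposited series values. The count was 38 without deficient normal replicate 2, 69 without replicate 1, 68 and 88 without wild-type normal replicates 1 and 2, and 470 without either deficient tumor array. It was 641 with array weights, 624 with the arrays of the 2 groups alone, 193 without a filter on dim probes and 144 with probes detected on all 8 arrays. Of 25 named genes that passed, 10 kept their call whichever array was left out. Small intestine and proximal genes were the clearest list, with Hoxb6, Sis (at least 3.66-fold) and Cyp4b1 (at least 6.84-fold) higher among 5 measured (3 adjusted over the list alone; median 3.02; camera adjusted p = 1.10e-04 with the preset and 0.297 with an estimated correlation; fry adjusted p = 0.00893). Of 5 distal colon genes only Hoxa13 fell (1 fell and 1 rose adjusted over the list alone; median −0.68, the value of Hoxd12, which was below background in both groups; adjusted p = 0.143).

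Camera with the preset correlation called several immune lists lower in deficient normal colon, and none of these calls held with an estimated correlation. Among 24 cytokines and chemokines Il1rn, which fell by 2.61, and Il18 fell (4 adjusted over the list alone; median −0.44; adjusted p = 4.82e-04 with the preset and 0.436 with an estimated correlation). S100a8 fell by 3.87 (adjusted p = 0.00849), the only one of 11 neutrophil genes to pass (3 adjusted over the list alone; median −0.79; adjusted p = 0.443 with an estimated correlation), and with Pla2g2f (at least 1.61-fold) it fell among 13 Paneth and antimicrobial genes (3 adjusted over the list alone; adjusted p = 0.436 with an estimated correlation). Fcmr (at least 1.68-fold) fell among 13 B and plasma cell genes (5 adjusted over the list alone; median −1.02; adjusted p = 0.446 with an estimated correlation). None of 22 interferon-stimulated genes passed (2 fell and 1 rose adjusted over the list alone; median −0.66; adjusted p = 0.446 with an estimated correlation), nor any of 7 mast cell genes (2 fell adjusted over the list alone; adjusted p = 0.436 with an estimated correlation). Absorptive colonocyte genes were mixed, with Atp12a, Scnn1g (at least 3.45-fold) and Scnn1a (−2.04) lower and Tmigd1 (3.04) higher (5 fell and 1 rose adjusted over the list alone; adjusted p = 0.443 with an estimated correlation). The glycolytic enzymes Pfkp and Hk1 fell by 1.44 and by 1.37 (4 adjusted over the list alone; adjusted p = 0.436 with an estimated correlation). Called higher with the preset correlation were enteric neuron and glia genes (median 1.37, 5 adjusted over the list alone; adjusted p = 0.436 with an estimated correlation), adipocyte genes with Acvr1c (median 1.34, 3 adjusted over the list alone; 0.443), smooth muscle genes (median 0.53, 2 adjusted over the list alone; 0.618) and cell cycle genes with Kif11 (median 0.48, 1 adjusted over the list alone; 0.541). The cell cycle call ended without wild-type normal replicate 1 (adjusted p = 0.201) or deficient normal replicate 1 (0.260), and the Paneth (0.122) and mast cell calls (0.0687) without deficient normal replicate 1.

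Between tumors, single genes of neutrophils, Wnt targets, Paneth cells and squamous epithelium were higher and colonocyte genes lower in the deficient mice. Mmp7, a Paneth cell protease, was at least 27.0-fold higher (SE of its log2 difference 1.16, adjusted p = 0.0201, n = 2 arrays each), the alpha-defensin Defa20 was higher by 7.04 (SE 1.59, adjusted p = 0.0239), Defa26 at least 19.2-fold (adjusted p = 0.0479) and Itln1 by 5.31 (SE 1.08, adjusted p = 0.0178). The Wnt target Sp5 was at least 40.1-fold higher (adjusted p = 0.0123). S100a9 was higher by 5.92 (SE 0.77, adjusted p = 0.00511), Stfa1 at least 19.1-fold and Retnlg at least 20.5-fold. The squamous genes Lor (7.05, SE 0.31, adjusted p = 2.10e-04), Calm4 (5.88), Krtdap (5.85) and Rptn (5.42) were also higher. Car4 fell by 7.12 (SE 1.09, adjusted p = 0.00779) and Aqp8 by 7.01 (SE 0.62, adjusted p = 0.00178). Other falls were in Sycn (−6.18), Cyp2d12 (−5.93), Tgm3 (at least 31.3-fold), Cyp2d9 (−5.56), Cyp2c55 (−5.37), Hao2 (−5.18), Cyp2c67 (−5.05), Slc13a2 (−4.97), Selenbp1 (−4.88) and Sult1d1 (−4.76). Il1b was higher by 4.01 (SE 0.71, adjusted p = 0.0115), Casp1 fell by 1.05 (SE 0.25, adjusted p = 0.0282) and Il18 by 1.61 (SE 0.41, adjusted p = 0.0345). Both deficient arrays lay on the same side of both wild-type arrays for each of these, which the rule required of all but Il1b, Casp1 and Il18. In wild-type tumors no probe passed against normal colon, and the Wnt target median stood at −0.23 and −0.62 from the wild-type normal mean. A genotype difference in tumors was thus not told apart from a weaker tumor profile in the wild-type samples. Of the 1160 rises in deficient tumors over normal colon 548 were also called here, and of the 1421 falls 671. Both comparisons use the same deficient tumor arrays.

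In all, 1013 probes were higher (826 genes) and 1448 lower (1075 genes) in the deficient tumors. The count was 1116 without deficient tumor replicate 1 and 1486 and 1190 without wild-type tumor replicates 1 and 2. It was 765 with the arrays of the tumors alone and 1441 with array weights. Of 27 named genes that passed, 15 kept their call whichever array was left out. Defa20, Defa26, Mmp7, Itln1, Sycn, Sult1d1, Casp1 and Il18 were not called without either wild-type tumor array, Sp5, Rptn and Slc13a2 without replicate 2 of these. Krtdap was not called without deficient tumor replicate 2. Casp1 and Il18 were lost without deficient tumor replicate 1 (adjusted p = 0.110 and 0.118) or 2 (0.0584 and 0.0672) as well. Il18 and Sycn were also lost without either wild-type normal array, and Sycn and Defa26 without either deficient normal array. Without deficient tumor replicate 1 the calls of Defa20, Defa26, Mmp7 and Itln1 were lost too, with a fitted log2 difference of 3.16 for Defa26 against 5.45 with all arrays. Sycn had an SD of 4.11 in the deficient tumors and was above background on 1 of the 2.

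Wnt target genes were higher in 11 of 14 (12 rose and 1 fell adjusted over the list alone; median 2.86; adjusted p = 0.355 with an estimated correlation), with Sp5, Notum (5.22), Wif1 (4.09) and Prox1 (3.72). Cell cycle genes were higher in 15 of 22 (18 adjusted over the list alone; median 1.25; 0.319), with Mcm2 (1.99), Birc5 (1.79) and Top2a (1.65). Higher too were 15 of 24 cytokines and chemokines, with Il18 lower (19 rose and 3 fell adjusted over the list alone; 0.140), 9 of 11 neutrophil genes (9 adjusted over the list alone; 0.140), 11 of 14 matrix proteases (11 adjusted over the list alone; 0.140), 5 of 7 mast cell genes (6 adjusted over the list alone; 0.140) and 7 of 13 Paneth and antimicrobial genes, with Pigr lower (9 rose and 1 fell adjusted over the list alone; 0.148). Each value closing a bracket is the adjusted p with an estimated correlation. Absorptive colonocyte genes were lower in 15 of 20 (16 fell and 1 rose adjusted over the list alone; 0.140), xenobiotic metabolism genes in 17 of 22 (18 fell and 2 rose adjusted over the list alone; 0.148), fatty acid oxidation genes in 9 of 16 (11 adjusted over the list alone; 0.148), B and plasma cell genes in 6 of 13 (9 adjusted over the list alone; 0.463), smooth muscle genes in 6 of 15 (10 adjusted over the list alone; 0.496) and enteroendocrine genes in 3 of 12, with Isl1 higher (8 fell and 1 rose adjusted over the list alone; 0.463). Among the immune genes Fcmr fell by 2.58 and Cxcr5 by 2.34. Of 5 blood genes Hba-a1 (4.94) and Alas2 (at least 5.11-fold) were higher (3 adjusted over the list alone; 0.355). Endothelial genes had a median of 0.59, with Egfl7, Cdh5 and Esam higher (4 adjusted over the list alone; 0.625), a call that ended without deficient tumor replicate 2 (adjusted p = 0.413). Squamous genes were higher in 10 of 32 (13 adjusted over the list alone; median 2.81; 0.597).

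The tumor difference itself depended on genotype for 521 probes (206 with a positive and 315 with a negative interaction; 172 and 250 genes). Positive ones made up 39.5%, but 49.0% with median scaling, 52.6% without deficient tumor replicate 1, 60.9% without wild-type normal replicate 2 and 69.6% without deficient normal replicate 2, so the balance of signs was not stable. The largest positive interactions were in S100a8 (8.79, SE 0.66, adjusted p = 0.00446), S100a9 (8.73, SE 1.09, adjusted p = 0.0116), the homeobox gene Evx1 (7.52, SE 0.77, adjusted p = 0.00765), Itln1 (7.50, SE 1.53, adjusted p = 0.0433), Mmp10 (7.47, SE 0.81, adjusted p = 0.00790) and Cxcl1 (6.99, SE 1.00, adjusted p = 0.0166). Interactions were negative for Cyp2c65 (−7.54, SE 0.70, adjusted p = 0.00544) and Cyp2c55 (−6.91, SE 0.65, adjusted p = 0.00571). Interaction values include probes near background in some groups and are not fold changes. The count was 49 and 23 without deficient normal replicates 1 and 2, 100 and 115 without wild-type normal replicates 1 and 2, 338 and 125 without wild-type tumor replicates 1 and 2, and 1141 without deficient tumor replicate 2. It was 347 with median scaling, 297 without a filter on dim probes and 329 with probes detected on all 8 arrays. Among 24 named genes 5 kept their call whichever array was left out.

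By list, positive interactions were called among cytokines and chemokines for 10 of 24 (18 adjusted over the list alone; median 2.49), neutrophil genes for 7 of 11 (9 adjusted over the list alone; 3.81), matrix proteases for 6 of 14 (11 adjusted over the list alone; 2.35), Paneth and antimicrobial genes for 4 of 13 (8 positive and 1 negative adjusted over the list alone; 2.36) and mast cell genes for 3 of 7 (6 adjusted over the list alone; 1.64). Negative ones were called for 4 of 16 fatty acid oxidation genes (11 adjusted over the list alone; −1.23) and 3 of 5 small intestine and proximal genes (4 adjusted over the list alone; −3.35). For each of these lists the adjusted p was 0.0693 with an estimated correlation. Xenobiotic metabolism genes had negative interactions in 11 of 22 (15 adjusted over the list alone; adjusted p = 0.135 with an estimated correlation) and absorptive colonocyte genes in 5 of 20, with Atp12a positive (13 negative and 1 positive adjusted over the list alone; adjusted p = 0.234 with an estimated correlation). Lgr5 (4.14) and Ascl2 (2.64), both markers of intestinal stem cells, were called among 14 Wnt target genes (11 positive and 1 negative adjusted over the list alone; median 3.38; adjusted p = 0.306 with an estimated correlation). The blood call (median 3.07, adjusted p = 0.0453 with the preset and 0.373 with an estimated correlation) ended without any of wild-type normal replicate 1 (0.0800), either deficient normal array (0.0733 and 0.0611) or deficient tumor replicate 1 (0.165). The neighbours of Casp12, with Mmp10 and Mmp13 called (5 positive and 1 negative adjusted over the list alone), had a median of 0.39 (adjusted p = 0.0453 with the preset and 0.50 with an estimated correlation), a call that ended without deficient normal replicate 1 (0.254) or wild-type tumor replicate 2 (0.181). Smooth muscle genes had a median of −1.83 (11 negative adjusted over the list alone; adjusted p = 0.373 with an estimated correlation), and enteric neuron and glia genes one of −1.65, with none of 8 called (7 negative adjusted over the list alone; 0.373). Macrophage genes had a median of 0.78, with Fcer1g (2.24) and Cd14 (1.99) called among 17 (4 positive and 1 negative adjusted over the list alone; adjusted p = 0.372 with an estimated correlation). Cell cycle genes had one of 0.86, with Mcm2 (1.76) called among 22 (1 adjusted over the list alone; 0.385). Squamous genes had a median of 3.30, with Cdsn (4.60), Hrnr (3.87) and Krt1 (2.87) called among 32 (4 adjusted over the list alone; adjusted p = 4.09e-08 with the preset and 0.672 with an estimated correlation).

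**Figure D2:**
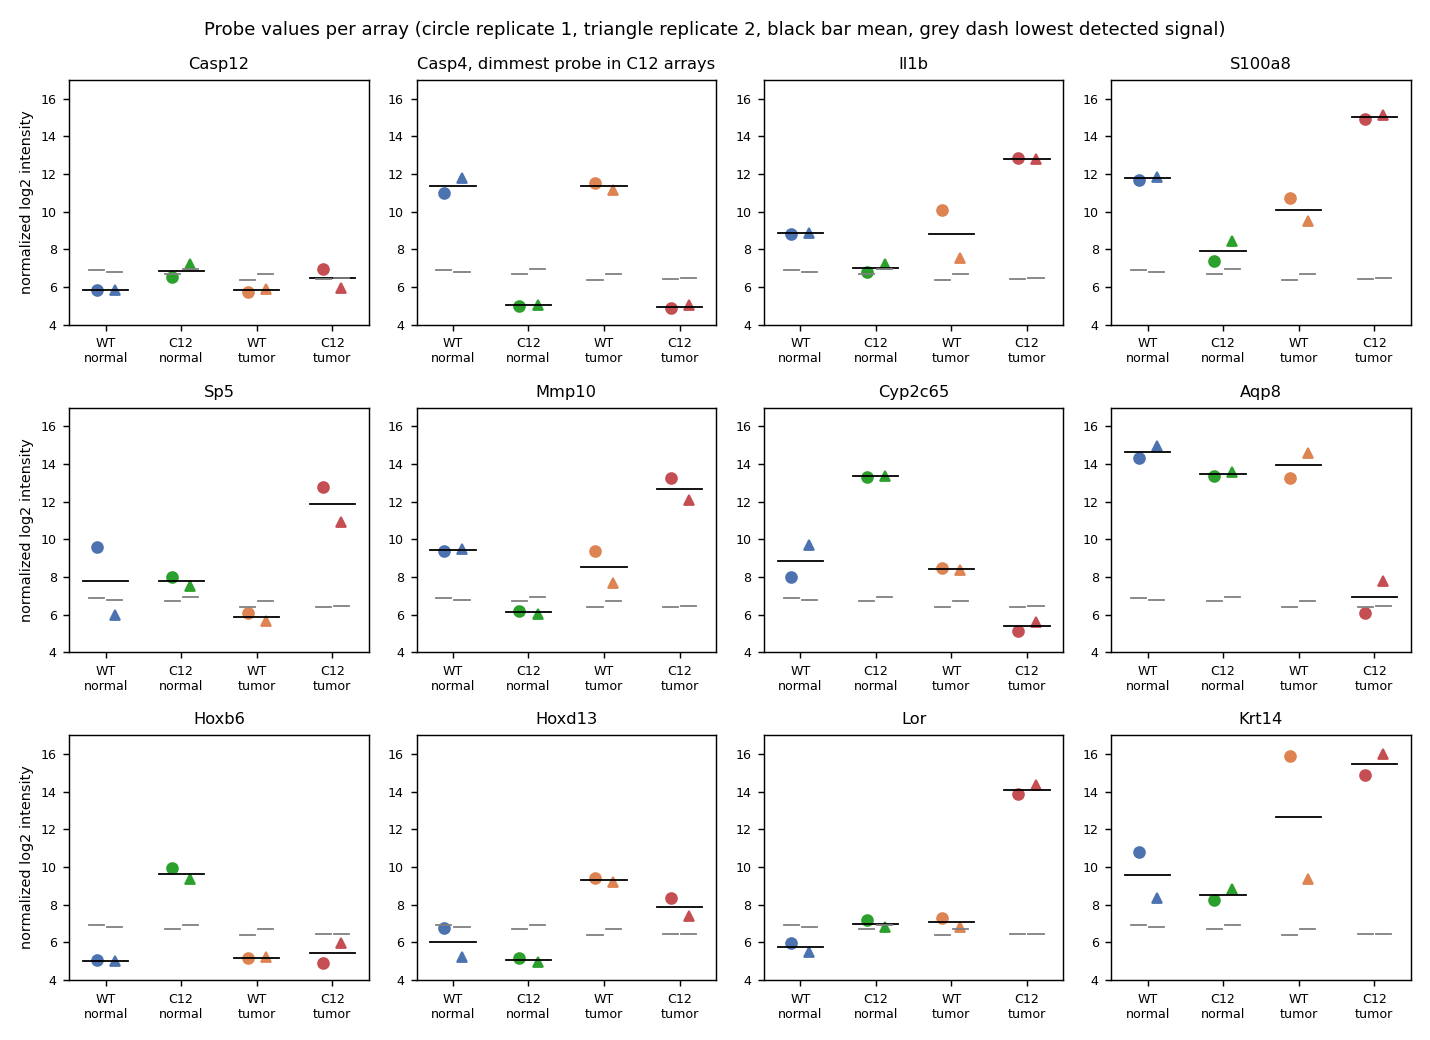
Normalized log2 intensity of 12 genes on each array, with circles for replicate 1, triangles for replicate 2, a black bar for the group mean and a grey dash at the lowest intensity called above background. Casp12 lay below or close to the dash on every array, and Krt14 stood at 15.9 in wild-type tumor replicate 1 and at 9.39 in replicate 2.

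With both genotypes in an additive model, 7 probes differed between tumor and normal colon. They are named here after their values were seen. Fcmr (3.67), Dusp2 (2.16), Clu (2.12), Snn (1.95), Scnn1g (1.58) and the unnamed probe ILMN_2598402 (1.53) were higher and Azgp1 fell by 1.45, with adjusted p from 0.0326 to 0.0464. This count was 0 without background correction and 0 with a replicate block. With median scaling it was 612, of which 82 were higher and 530 lower. It was 30 and 3 without wild-type normal replicates 1 and 2, 0 without either deficient normal array, 0 and 1182 without wild-type tumor replicates 1 and 2, and 3 and 0 without deficient tumor replicates 1 and 2. With both tissues in one model, 215 probes were higher and 594 lower in deficient mice, and the count fell most, to 87, without deficient normal replicate 2. It was 192 and 366 without wild-type normal replicates 1 and 2, 164 and 124 without wild-type tumor replicates 1 and 2, and 310 and 232 without deficient tumor replicates 1 and 2.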

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

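The tests of the Wnt target genes by wild-type tumor array, of the genotype ratio by direction and of the skeletal muscle genes by deficient tumor array, the comparison of B and plasma cell genes with each normal array, and the test for a smaller share of neighbouring genes were chosen after the result was seen. The remaining tests were written before the values they measure were seen. The lymphoid and position tests met, and the neighbouring genes missed, the rules written beforehand; these 3 and the Wnt test are read here by stricter rules set after the values were seen, which leave each of them open.

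A difference between the genotypes in their tumor minus normal change marked 521 probes by the interaction test in limma (n = 2 arrays per group). The genes with the largest positive interaction were S100a8 (8.79), S100a9 (8.73), the homeobox gene Evx1 (7.52), Itln1 (7.50), Mmp10 (7.47), Cxcl1 (6.99), Retnlg (6.69), Wfdc18 (6.50), Hdc (6.43), Trim10 (6.11), Krt90 (5.90) and Il1b (5.85). The most negative were Cyp2c65 (−7.54), Cyp2c55 (−6.91), Sult1d1 (−6.31), Osr2 (−6.20), Aqp8 (−5.84), Slc51a (−5.60), Defb37 (−5.59), Hao2 (−5.52), Hkdc1 (−5.39), Selenbp1 (−5.27), Ugt2b36 (−5.17) and the brush border protease Mep1a (−5.01). An interaction can come from the normal tissue as well as from the tumors.

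No probe passed between wild-type tumors and normal colon, and replicate 2 of the wild-type tumors resembled normal colon. If that array alone lacked the tumor profile, Wnt target genes should have been high in replicate 1, where their median stood at −0.23 (−0.62 in replicate 2), against 0.63 and −0.63 in the wild-type normal arrays and 3.03 and 2.23 in the deficient tumors. Without replicate 2, however, the fitted differences in wild-type mice included Trp63 (6.65), Col17a1 (5.86) and Sct (−4.39). The explanation thus stays open for differences other than the Wnt genes. Replicate 1 also stood high for squamous (2.94) and skeletal muscle genes (2.67), and Trp63 is in the squamous list. These differences were not told apart from such tissue in that sample. Lymphoid tissue in both wild-type tumor samples was tested with the 10 B and plasma cell genes not seen beforehand, whose median was 0.750 in the lower array and 0.785 in the other, against −0.706 and 0.706 for the same genes in the wild-type normal arrays. The tumor medians lay barely above the higher normal array, which leaves the presence of lymphoid tissue open. A rise of these genes in both tumors would by itself add calls. Whether lymphoid tissue in the samples could also hide other differences was not tested. No further explanation was tested for this pattern.

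The genotypes differed in normal colon at 292 probes, among them genes that mark position along the gut. If the pieces came from different positions, proximal genes should be higher and distal genes lower in deficient colon: without the genes seen beforehand the medians were 1.96 over 4 proximal and −0.68 over 3 distal genes, 2.63 apart (the proximal median was 1.38 with genes at background set to their bound). This leaves positions open, because the distal median is the value of Hoxd12, which like Hoxc10 was below background in both groups, and of the measured distal genes Hoxa13 was lower and Hoxd10 higher (2.20). If the genotype itself acted in both tissues, the same probes should differ between tumors. The difference there was 0.253 of that in normal colon, which leaves this open. By direction it was 0.0323 for the 134 higher probes, which as a set hardly differed that way between tumors, and 0.564 for the lower probes. Of the higher probes 108 also fell from normal colon to tumor in deficient mice, which can remove a genotype difference there. The ratios therefore do not tell the genotype apart from the tumor change. A chromosome segment around the targeted gene stays open: 2 of the 55 tested neighbouring genes (Casp4 and Fut4), or 3.64%, passed over both tissues against 5.30% of 9282 other genes (one-sided Fisher exact p = 0.796 for a larger share and 0.437 for a smaller one), and the Casp4 probe ILMN_2811737, at least 23.7-fold lower in deficient normal colon, was not the one tested.

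Genes of the cornified envelope were high in deficient tumors. The squamous epithelium list, of which most members were not seen beforehand, had a median difference of 5.06, consistent with squamous tissue of the anal margin or skin in those samples, or with squamous change in the tumors, which was not tested. Skeletal muscle of the anal region was tested with a muscle list, whose median of 3.36 met the rule written beforehand. By array, however, the median stood at 6.98 in deficient tumor replicate 1 and at −0.33 in replicate 2, and the requirement that both arrays show it was set after these values were seen. Among the deficient tumors muscle genes were thus high in replicate 1 alone. Squamous genes stood at 3.45 in deficient tumor replicate 1 and at 6.09 in replicate 2. In the wild-type tumors both were high in replicate 1 (squamous 2.94, muscle 2.67) and not in replicate 2 (−0.11 and 0.32). The anal region thus stays open for replicate 1 of each genotype. Low muscle genes cannot exclude anal tissue taken without muscle, so it stays open for deficient tumor replicate 2 as well.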

How the results depend on the processing

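The comparison of deficient tumors with wild-type normal colon was chosen after the data were seen, and all other alternatives were chosen before. Array weights gave 641 probes for the genotypes in normal colon and 1441 in tumors, and models of the compared arrays alone gave 624 and 765. Without a filter on dim probes the count was 193 in normal colon and 297 for the interaction, and with probes detected on all 8 arrays 144 and 329, where fewer probes were tested. Median scaling gave 347 for the interaction. For tumor against normal over both genotypes the count was 0 without background correction, 4 with an offset of 50, 612 with median scaling, 3 with cyclic loess and 2 with probes detected on all 8 arrays. The median of all probes was −0.27 in wild-type mice, −0.26 in deficient mice and −0.24 over both with median scaling, and 0.12, 0.11 and 0.12 with the deposited values, against −0.00, −0.02 and −0.01. A replicate block gave 0 over both genotypes, 462 for the genotypes over both tissues, and otherwise 0, 2650, 281, 2561 and 498, though replicates of different groups share only a number. Leaving out each array in turn gave 0 to 105 for tumors in wild-type mice, 809 to 2709 in deficient mice, 38 to 470 for the genotypes in normal colon, 1116 to 2082 in tumors, 23 to 1141 for the interaction, 0 to 1182 for tumors over both genotypes and 87 to 636 for the genotypes over both tissues. Directions turned for glycolysis in wild-type tumors with median scaling (−0.64), and for B and plasma cell genes there with probes detected on all 8 arrays (0.00, or 0.00286 before rounding, with the test pointing the other way). With single arrays left out they turned for squamous genes in wild-type tumors (−0.11 to 2.94), T cell genes between genotypes in normal colon (−0.45 to 0.77), and skeletal muscle genes between tumors (−1.64 to 5.46) and in the interaction (−1.77 to 5.33). The cell cycle median in wild-type tumors went from −0.31 to 0.03 without wild-type normal replicate 2 (adjusted p = 0.951). For all of these the cause was not tested. Deficient tumors against wild-type normal colon gave 2901 probes, of which 704 rises and 868 falls were shared with the comparison within deficient mice, which uses the same tumor arrays. Calls of named genes and of lists were counted once per comparison, so a gene or list can count more than once. Of 100 such gene calls 99 were kept with an offset of 50, 98 with the deposited values, 94 with median scaling and 71 without the filter, and none turned. Of 85 list calls 79 were kept with median scaling, 82 with the deposited values and 37 with fry. With probes detected on all 8 arrays 73 of the list calls could be tested, of which 51 were kept and 1 turned. Signal over background limits the range of fold changes that could be measured.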

Other observations

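Of what follows, the test with splits of the 8 arrays was written before the result was seen, except where stated. The other values are descriptive and were not part of a test written beforehand. The red cell genes Hba-a1 and Alas2 were high in both deficient tumors, where the blood list stood at 4.88 and 2.48 log2 units above wild-type normal colon. The distal colon list stood at 2.31 and 2.43 in the wild-type tumors, at 2.35 and 1.41 in the deficient tumors, and at −0.83 and −1.03 in deficient normal colon. Arg1 stood at 14.07 in wild-type tumor replicate 1 and at 6.32 in replicate 2. The macrophage list, of which it is a member, stood at 0.08 and 0.44 log2 units above wild-type normal colon there. Acta1, the skeletal muscle actin, stood at 15.11 in deficient tumor replicate 1 and at 7.78 in replicate 2. In deficient normal colon 2 probes without a gene symbol, picked after their values were seen, were higher than in wild type, ILMN_3118071 at least 41.5-fold (adjusted p = 1.40e-04) and ILMN_1220244 at least 13.5-fold (adjusted p = 1.64e-04), with both deficient arrays higher.

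Of the 1160 probes that rose in deficient tumors 762 had the same sign in wild-type tumors, as had 989 of the 1421 that fell, and the tumor differences of the genotypes, which share no arrays, correlated at r = 0.318 across probes, which are not independent replicates. Of the 158 probes lower in deficient normal colon 86 were also called lower in deficient tumors, against 17.2 if the calls were independent. Of the 134 higher ones 18 were also called higher, against 10.2. Both comparisons share a model and its spread per probe, so their calls are not independent even without a shared difference.

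Whether chance could give these counts was tested by refitting the additive models with every other split of the 8 arrays into 4 and 4 that could be fitted. For tumor against normal over both genotypes, 1 of 34 splits, the real one, gave as many as 7 probes, and the highest other split gave 0. Other splits carry the real differences in their residual spread, so they were refitted, after the result was seen, with both real differences kept in the model. Of 32 such splits 1 then gave 9 probes, and the split that equals the interaction gave 521. For the genotypes over both tissues, 1 of 34 splits, again the real one, gave 809 probes, and the highest other split gave 7. The rule written beforehand, on the 34 splits alone, was met by both counts, but only 3 splits (tumor, genotype and interaction) keep the replicates of each group together, and these are too few for a share under 0.05.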
